A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

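Per the labels, the samples are yeast with a plasmid for HA-tagged αENaC (3 arrays) and yeast with a vector control (7 arrays), grown at 26 °C in selective medium. Per the labels' protocols, RNA was extracted with hot phenol and cleaned on a column, and biotin-labelled cRNA was made with the Affymetrix 3' IVT Express kit. Per the series' design text, each strain had at least 3 biological replicates; the arms expressing CFTR and Kir2.1 were not analysed here. The deposited value of each probe set is a score: from the values, a z score within each array, with mean 0 and SD 1 over 10715 probe sets, of what look like linear intensities. How the authors summarised and background-corrected the probe values is not given in the sources used here. The design written before the data were examined assumed log2 or linear values, so the transformation below was chosen after the unit was seen.

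Each array's z scores were turned into units of the array mean by subtracting the array's lowest score and dividing by the size of that lowest score. This takes the lowest value as 0 and leaves any additive background unknown. Then 0.03 was added, log2 was taken and the arrays were quantile normalized over all 10715 probe sets. A log2 difference is on this log2(value + 0.03) scale and understates the change of low genes. Names came from the platform annotation, with symbols updated through gene identifiers from the R64 RefSeq gene table, which was used for names alone. Of the probe sets, 5498 name 1 S. cerevisiae gene (5449 genes), 1746 have names outside the S. cerevisiae annotation, 3470 are unnamed here and 1 names several genes. The 95th percentile of the 1746 gave a background of −2.03 on the log2 scale, and 4959 of the 5498 lay above it on average. For 128 probe sets the identifier marks probes shared between sequences, among them that of AAD4. TDH3 was the brightest probe set on every array after quantile normalization, so its difference could not be measured. The αENaC transcript itself is not measured here, so the labels were not checked against it, and ENA1 was not analysed here.

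Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariates, 8 residual degrees of freedom, Benjamini-Hochberg over the 5498 probe sets, threshold 0.05). Errors of differences are SE and n is 3 αENaC and 7 control arrays. The 29 gene lists (986 of 1011 symbols measured) were fixed before the data were examined, as were the main test, the rule for named genes and most alternatives. The lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, on ranks and with fry, adjusted over the 29 lists. A list's median takes the probe set with the smallest p per gene, and within-set values compare 2 with 2 arrays in set 1 and 1 with 1 in set 2. The text names the 12 largest rises and 12 largest falls past the threshold whose groups do not overlap, up to 3 members with the smallest p of each list, and a fixed choice of ER, heat-shock, transport, stress and marker genes.

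The labels do not call the title number sets batches, but the arrays split by them, so the set was fitted as a fixed and as a random block (duplicateCorrelation, correlation 0.716). Replicate numbers 1 to 3 occur in both groups. Across probe sets, the deviations of same-numbered arrays from their group means correlated at 0.41, 0.22 and 0.17, each over 0.1, so the numbers were taken to pair the samples. Arrays with other numbers correlated as much: αENaC 1 with control 2 at 0.38, αENaC 2 with control 1 at 0.27, and αENaC 3 with controls 5 to 7 at 0.39, 0.40 and 0.31. The replicate block holds the 3 αENaC arrays and controls 1 to 3, leaves out controls 4 to 7 and has 2 residual degrees of freedom. Arrays within a set and group were near-identical (αENaC 1 and 2 at r = 0.999) except control 4, which correlated with controls 5 to 7 at 0.983, 0.980 and 0.985 and was kept apart in averaging. So p-values measure the spread between these arrays, which may be in part technical. Other alternatives changed the scaling, pseudocount, background floor, filter on dim probe sets, variance model, array weights, probe sets tested and arrays used, with each array left out in turn.

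The steps were tested on simulated data with the real levels and changes added to 67, 67 and 66 of the 5498 probe sets per size. For αENaC against control, 59.7%, 79.1% and 98.5% of changes of 0.5, 1 and 2 on the log2 scale were recovered with 6 false calls. With a simulated set effect the shares were 38.8%, 83.6% and 97.0% with 0 false calls, and 83.6%, 95.5% and 100% with 7 false calls when the set was a block. In both, noise was drawn independently for each array, with no effect shared by arrays of the same set and group. Most real arrays of a set and group were near-identical, so these counts do not bound the false calls in the real data. The list test called the 1 shifted list and 0 others. That simulation drew each gene independently and without a set effect. So it cannot show how the list test behaves on genes that move together. The precision of the arrays is limited by their number.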

Results

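Gene expression was measured in Saccharomyces cerevisiae that carried a plasmid for the α subunit of the epithelial sodium channel (αENaC). Yeast with a vector control served as the comparison. Cultures grew in selective medium at 26 °C to mid log phase. Biotin-labelled cRNA from total RNA was hybridised to single-colour arrays. There were 3 αENaC arrays and 7 control arrays. The sample titles carry running numbers. αENaC 1 and 2 with controls 1 and 2 hold 1 to 4 (set 1). αENaC 3 with control 3 holds 5 and 6 (set 2), and controls 4 to 7 hold 11 to 14 (set 3). Across probe sets, which are not independent replicates, arrays of the same group correlated at a median r of 0.997 within a set and 0.959 between sets. Arrays of different groups within a set correlated at a median of 0.977. The first principal component held 53.7% of the variance and ordered the arrays by set. It lay at −20.4 to −12.8 in set 1, −2.2 and 2.1 in set 2, and 13.6 to 21.8 in set 3. Since set 3 holds controls alone, this component is partly confounded with the comparison. On each array the S. cerevisiae probe sets had a median signal 25.6 to 44.4 times that of the probe sets named outside its annotation. This ratio depends on taking each array's lowest score as 0. The number of arrays limits the precision.

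The comparison of αENaC with vector control yeast asks which yeast genes differ when the channel subunit is present. The largest rise was in ULI1, a gene induced by the unfolded protein response, which was 2.31 ± 0.14 higher on the log2 scale (SE, n = 3 and 7; adjusted p = 5.63e-05), or 4.97-fold. INO1, which encodes the enzyme that makes inositol phosphate for phospholipid synthesis, rose by 1.76 ± 0.26 (adjusted p = 0.0121), or 3.39-fold. ERO1, the oxidase that drives disulfide bond formation in the endoplasmic reticulum (ER), rose by 0.89 ± 0.09 (adjusted p = 0.00126). The largest fall was in the ammonium permease gene MEP2, at −1.16 ± 0.21 (adjusted p = 0.0266), followed by SPL2, a gene of the phosphate response, at −0.95 ± 0.08 (adjusted p = 0.000507). In all, 75 probe sets (74 genes) rose and 20 (20 genes) fell among the 5498 tested. With the replicate number as a block limma called none of them. That fit used 3 against 3 arrays, without controls 4 to 7, and had 2 residual degrees of freedom. At an unadjusted p under 0.05 it had 1127 probe sets, against 998 in the main fit, and its lowest adjusted p was 0.0951.

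RTA1, a membrane protein gene, rose by 1.45 ± 0.26 (adjusted p = 0.0221). ADR1, an activator of glucose-repressed genes, rose by 1.37 ± 0.16 (adjusted p = 0.00318), and the serine deaminase gene CHA1 by 1.30 ± 0.22 (adjusted p = 0.0165). The sugar phosphatase gene DOG1 rose by 1.22 ± 0.14. YOR338W rose by 1.15 ± 0.08, PRM5 by 1.02 ± 0.17, SRD1 by 0.99 ± 0.18 and YLR108C by 0.94 ± 0.16. Adjusted p for these 5 genes ran from 0.000133 to 0.0278. The meiotic genes HOP1, at 1.40 ± 0.13, and NDJ1, at 1.23 ± 0.24, also passed the test. HOP1 lay below the background level in the controls, and NDJ1 lay below it in both groups. The phospholipase gene PLB2 fell by 0.93 ± 0.20 and INA1 by 0.79 ± 0.16. The mating-type switching endonuclease gene HO fell by 0.74 ± 0.11 and the ester synthesis gene EEB1 by 0.69 ± 0.09. FAR1, an inhibitor of the cell cycle in mating, fell by 0.58 ± 0.12. OPT1, FMC1, RAD27, NNF1 and MEH1 fell by 0.55, 0.54, 0.53, 0.51 and 0.49. These 24 genes were chosen among those on which every αENaC array lies on 1 side of all 7 controls, so their shared sign in sets 1 and 2 follows from the choice.

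**Figure D1:**
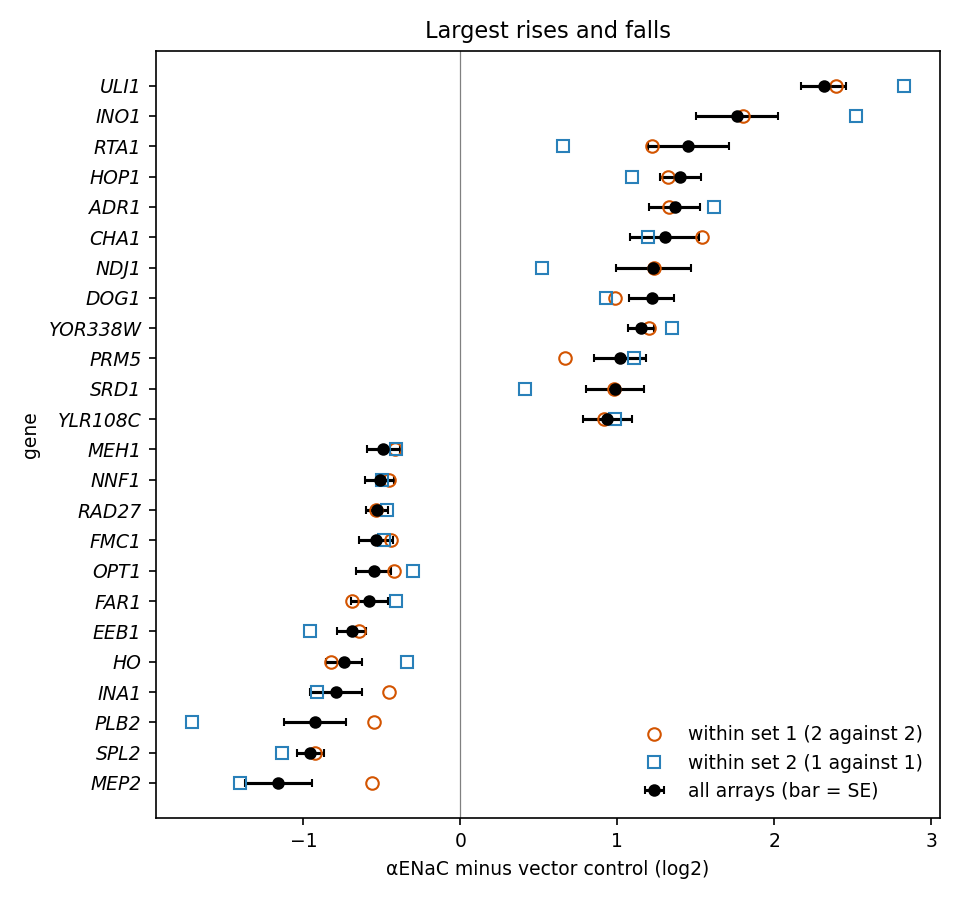
Log2 difference of αENaC from vector control for the 12 largest rises and 12 largest falls that passed the test, with the mean over all arrays and its SE (black), the difference within set 1 (circles) and the difference within set 2 (squares). Both within-set differences lie on the same side of 0 as the mean for all 24 genes, as their choice requires, and for ULI1 they are 2.39 and 2.83.

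ER chaperone and oxidative folding genes were higher as a group. Of 18 measured, 7 rose and none fell (12 and none when adjusted over the list alone), and 17 were positive. The median difference was 0.29 (adjusted p = 2.17e-09, and adjusted p = 0.0321 with an estimated correlation). It was 0.25 within set 1 and 0.27 within set 2. Besides ERO1, the nucleotide exchange factor gene SIL1 rose by 0.88 ± 0.12 (adjusted p = 0.00584). The J-domain protein gene JEM1 rose by 0.66 ± 0.08 (adjusted p = 0.00318) and the chaperone gene LHS1 by 0.49 ± 0.08 (adjusted p = 0.0165). KAR2, the main ER Hsp70, rose by 0.42 ± 0.07 (adjusted p = 0.0165), but was at −0.05 with each array centred on its median (adjusted p = 0.904; 3.13e-07 to 0.998 over 28 alternatives). The disulfide isomerase gene PDI1 was at 0.18 ± 0.07 (adjusted p = 0.224), and at −0.30 with median centring and −0.09 without quantile normalization. KAR2 and PDI1 are bright, so their values under those scalings also carry the narrower range of the set 1 arrays given below with the ribosomal protein genes.

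Of 59 measured targets of the unfolded protein response, 12 rose and none fell (20 and none when adjusted over the list alone), and 49 were positive. The median was 0.20 (adjusted p = 2.17e-09, and adjusted p = 0.0603 with an estimated correlation), but 0.0050 with median centring (adjusted p = 0.000380, in a range of 1.53e-15 to 0.0603 over 31 alternatives). It was 0.13 within set 1 and 0.10 within set 2. This list holds 14 of the 18 ER chaperone genes, KAR2, ERO1, LHS1, SIL1 and JEM1 among them. HAC1, the transcription factor gene of the response, was at 0.16 ± 0.11 (adjusted p = 0.438), and at −0.12 with median centring. The array reads HAC1 transcript level and not its splicing. Of 31 genes of ER-associated degradation, 5 rose and none fell (8 and none when adjusted over the list alone). Some of them, such as DER1, HRD1 and JEM1, are also in the unfolded protein response list, and JEM1 is also in the ER chaperone list. So the calls of DER1 and JEM1 are counted again here. The median of the 31 was 0.17 (adjusted p = 0.000136, and adjusted p = 0.252 with an estimated correlation), with 0.16 within set 1 and 0.02 within set 2. DER1, a membrane component of that pathway, rose by 0.53 ± 0.10 (adjusted p = 0.0278). ASI3, a subunit of a ubiquitin ligase of the inner nuclear membrane, rose by 0.45 ± 0.07 (adjusted p = 0.0158). The ubiquitin ligase gene HRD1 was at 0.20 ± 0.14 (adjusted p = 0.454). Genes of ER translocation and N-glycosylation, with 35 measured and none called (none when adjusted over the list alone), had a median of −0.03 (adjusted p = 0.505), which was 0.04 without quantile normalization and 0.12 on the deposited z scores. On the z scores the list was called higher (adjusted p = 0.0347, in a range of 0.0296 to 0.980 over 31 alternatives). It was called lower in set 1 alone (−0.10, adjusted p = 0.0296) and without αENaC 3 (−0.08, adjusted p = 0.0352). SSH1 was at −0.24 (adjusted p = 0.0797; 0.0202 with the set as a block, in a range of 2.82e-06 to 0.998 over 28 alternatives) and SEC63 at 0.28 (adjusted p = 0.104).

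**Figure D2:**
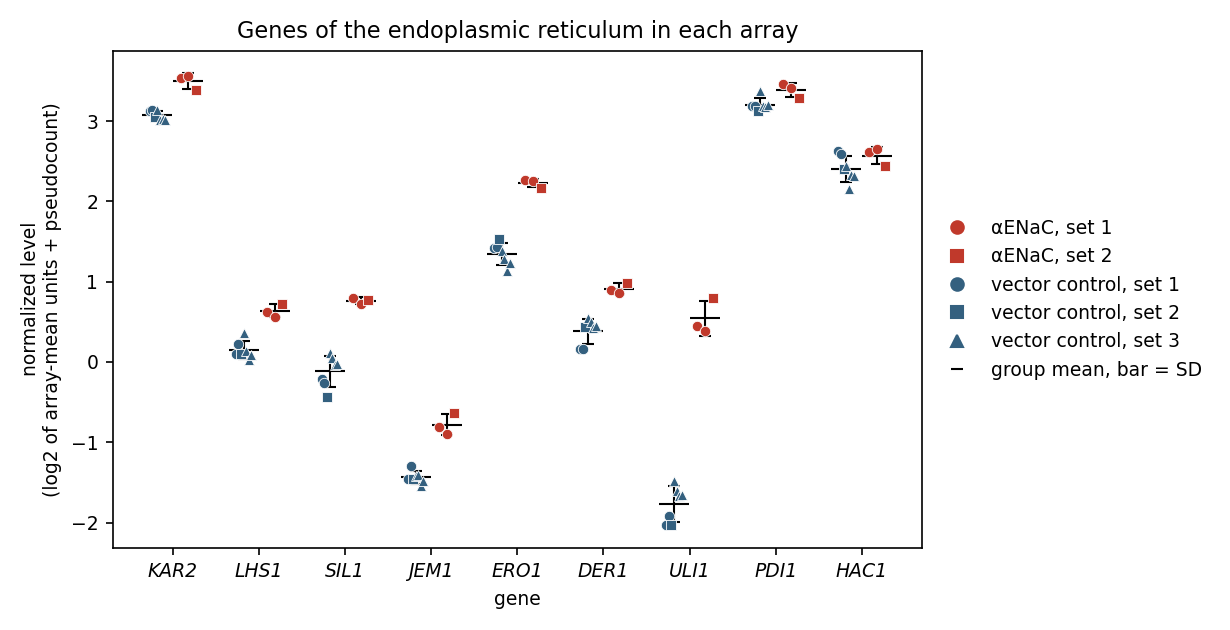
Normalized log2 level of 9 genes of the endoplasmic reticulum on each array, by group (colour) and title number set (shape), with group means and SD (n = 3 and 7). ULI1, ERO1, SIL1, JEM1, LHS1 and DER1 lie higher on all 3 αENaC arrays than on any control, as does KAR2, which is at −0.05 with median centring; PDI1 and HAC1 overlap between the groups and turn negative with median centring (PDI1 also without quantile normalization).

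Cytosolic heat-shock genes were higher as a group. Of 33 measured, 2 rose and none fell (20 and none when adjusted over the list alone), and 29 were positive. The median was 0.42 (adjusted p = 2.17e-09, and adjusted p = 0.234 with an estimated correlation), but 0.45 within set 1 and 0.03 within set 2. HSP82, an Hsp90 gene, rose by 0.84 ± 0.17 (adjusted p = 0.0392) and the Hsp70 gene SSA3 by 0.47 ± 0.07 (adjusted p = 0.0103). HSP82 passed under 15 of 28 alternatives (adjusted p from 8.92e-07 to 0.998). In set 2 its level was 2.36 in αENaC 3 against 2.27 in control 3, and that of SSA3 was −0.46 against −0.78. HSP104 was at 0.67 ± 0.19 (adjusted p = 0.107) and AHA1 at 0.53 ± 0.12 (adjusted p = 0.0588). AHA1 was called with the set as a block (0.34, adjusted p = 0.0176, in a range of 1.34e-06 to 0.998 over 28 alternatives). BTN2 was at 0.79 ± 0.36 (adjusted p = 0.276) and SSA4 at 0.79 ± 0.43 (adjusted p = 0.351). BTN2, SSA4 and HSP104 were higher in αENaC within set 1. In set 2 they were lower in αENaC 3 than in control 3 (2.30 against 2.60, 0.19 against 1.44 and 2.61 against 2.69). HSP26 was at −0.27 ± 0.93 (adjusted p = 0.908), with 2.26 within set 1 and −1.48 within set 2. Of 38 proteasome genes 1 rose and none fell (2 and none when adjusted over the list alone), and 34 were positive. The median was 0.18, against 0.05 within each set (adjusted p = 3.00e-06, and adjusted p = 0.368 with an estimated correlation). With median centring that call was lost (median 0.03, adjusted p = 0.0640, in a range of 2.54e-09 to 0.368 over 31 alternatives). The gene that rose was RPN4, the activator of proteasome genes, at 0.73 ± 0.12 (adjusted p = 0.0180).

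General stress genes, which respond to Msn2 and Msn4, had a median of 0.30 with 40 of 42 positive but none called (none when adjusted over the list alone). Their camera test passed (adjusted p = 0.00323), but adjusted p = 0.947 with an estimated correlation. It passed under 25 of 31 alternatives (adjusted p from 1.21e-19 to 0.947). The list split by set, with a median of 1.19 within set 1 and −0.30 within set 2. HSP12 was at 0.26 ± 0.73 (adjusted p = 0.885), and at −0.10 with median centring and −0.22 on the z scores. It was at 2.04 within set 1 and 0.59 within set 2, and with the set as a block it was called higher at 1.55 (adjusted p = 0.0117, in a range of 6.47e-05 to 0.998 over 28 alternatives). CTT1 was at 0.57 ± 0.45 (adjusted p = 0.522) and NTH1 at 0.61 ± 0.15 (adjusted p = 0.0735). The 122 cytosolic ribosomal protein genes were lower as a group, at a median of −0.06 (adjusted p = 2.67e-05, and adjusted p = 0.875 with an estimated correlation). The median was larger in size with other scalings, at −0.49 with median centring, −0.28 without quantile normalization and −0.40 on the z scores. Those scalings leave a difference between the sets in place. The 99th percentile of an array was 8.86 to 10.02 array means in set 1, against 12.09 to 13.62 on the other arrays. Set 1 holds 2 of the 3 αENaC arrays but 2 of the 7 controls, and these genes are bright. So the larger medians cannot be told apart from that difference and do not show a stronger fall. With quantile normalization the median was −0.10 within set 1 and 0.00 within set 2. The call was lost without αENaC 2 (median −0.032, adjusted p = 0.0552) and with near-identical arrays averaged (median −0.028, adjusted p = 0.0571, in a range of 8.65e-41 to 0.875 over 31 alternatives). Of the 122 genes, 22 were positive and none was called (none when adjusted over the list alone). RPS25A was at −0.22 ± 0.10 (adjusted p = 0.261). Ribosome biogenesis genes were at −0.03, with −0.51 within set 1 and 0.27 within set 2 (70 measured, none called and none when adjusted over the list alone; adjusted p = 0.111). With the replicate block they were called lower (adjusted p = 6.51e-05, in a range of 1.55e-18 to 0.980 over 31 alternatives), but not with an estimated correlation as well (adjusted p = 0.763). That all-array median was 0.13 without quantile normalization and 0.06 on the z scores. SPB1 was at −0.64 ± 0.18 (adjusted p = 0.0969).

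**Figure D3:**
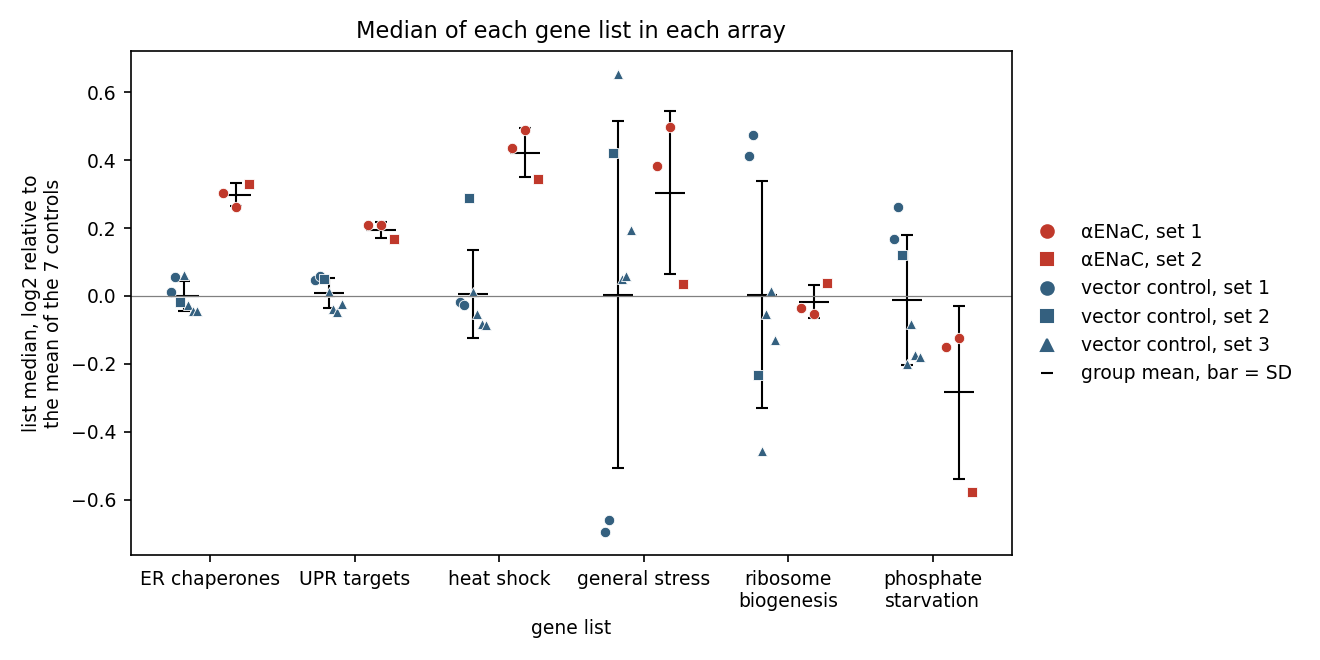
Median of 6 gene lists on each array, in log2 relative to the mean of the 7 controls, by group (colour) and title number set (shape), with group means and SD (n = 3 and 7). ER chaperone genes lie at 0.26 to 0.33 on the αENaC arrays and at −0.05 to 0.06 on the controls, while general stress genes range from −0.70 to 0.66 among the controls; the ribosome biogenesis median turns positive without quantile normalization and on the z scores.

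Phosphate starvation genes, which Pho4 activates, were lower as a group. Of 20 measured, 1 fell and none rose (4 and none when adjusted over the list alone), and 3 were positive. The median was −0.30 (adjusted p = 0.000239, and adjusted p = 0.419 with an estimated correlation). The call was also lost with fry (adjusted p = 0.0673) and with array weights, where the median turned to 0.08 (adjusted p = 0.561, in a range of 1.80e-08 to 0.561 over 31 alternatives). It was −0.46 within set 1 and −0.45 within set 2. SPL2 was the member that fell. PHO81 was at −0.42 ± 0.12 (adjusted p = 0.101) and PHM6, below background, at −0.79 ± 0.17 (adjusted p = 0.0516). With the set as a block 13 of the 20 were called lower. PHO81 (adjusted p = 0.00315, in a range of 0.000709 to 0.998 over 28 alternatives) and PHM6 (0.00203, in a range of 0.000263 to 0.989 over 27) were among them. Zinc and copper genes were lower as a group, at a median of −0.44 (adjusted p = 0.00119, and adjusted p = 0.653 with an estimated correlation). None of 19 was called, and 4 were lower when adjusted over the list alone. The medians within sets 1 and 2 were −0.023 and −0.23. The test did not pass with the set or the replicate number as a block (adjusted p = 0.693 and 0.396, in a range of 3.42e-06 to 0.865 over 31 alternatives). IZH1 was at −0.70 ± 0.16 (adjusted p = 0.0620) and the vacuolar zinc transporter gene ZRC1 at −0.44 ± 0.10 (adjusted p = 0.0638). With the set as a block both were called lower (adjusted p = 0.0176 and 0.0231, in ranges of 2.98e-06 to 0.989 and 3.36e-06 to 0.998 over 28 alternatives).

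The 25 measured genes of sodium, potassium and proton transport showed no shift past the test (adjusted p = 0.842), and none was called (none when adjusted over the list alone). Their median and mean were 0.03 against a test direction of lower, and the median was −0.10 with median centring. The potassium transporter gene TRK1 was at −0.33 ± 0.15 (adjusted p = 0.285). The proton pump gene PMA1 was at 0.05 ± 0.08 (adjusted p = 0.768), but at −0.43 with median centring, −0.22 without quantile normalization and −0.22 on the z scores. QDR2 was at 0.52 ± 0.16 (adjusted p = 0.138) and the sodium-proton antiporter gene NHA1 at −0.20 ± 0.07 (adjusted p = 0.185; 0.00019 on the z scores). Pyrimidine synthesis genes were higher as a group, at a median of 0.13 that was −0.0055 with median centring (adjusted p = 0.00323, and adjusted p = 0.662 with an estimated correlation). Of 13 measured, 2 rose and none fell (4 and none when adjusted over the list alone), and 12 were positive. The median was −0.05 within set 1 and 0.27 within set 2. The test did not pass with the set or the replicate number as a block (adjusted p = 0.298 and 0.436, in a range of 0.000419 to 0.884 over 31 alternatives). The CTP synthase gene URA8 rose by 0.93 ± 0.15 (adjusted p = 0.0165) and the dihydroorotase gene URA4 by 0.71 ± 0.14 (adjusted p = 0.0322). URA1 was at 0.66 ± 0.17 (adjusted p = 0.0782). URA3, the marker gene of plasmids of the pRS426 type, was at −0.02 ± 0.24 (adjusted p = 0.976), and at −0.45 within set 1 and −0.59 within set 2.

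The test was limma over 5498 probe sets at an adjusted p of 0.05, and 10 probe sets rose and 1 fell by at least 2-fold. The share of rises was 78.9% (75 higher, 20 lower), but 97.8% (45 and 1) without quantile normalization, where the median of all genes shifted by 0.16, and 95.7% (89 and 4) on the deposited z scores. With the set as a fixed block 406 probe sets rose and 377 fell, and with it as a random block 358 rose and 259 fell. All 95 calls kept their direction and passed in both. The spread in the fixed block comes largely from arrays within sets, most of them near-identical. Set 3, with controls alone, adds nothing to its difference. So the passing of the 95 is not independent support. With the fixed block the members called higher and lower were 10 and 1 of the ER chaperones and 17 and 2 of the unfolded protein response targets. They were 8 and 0 for both ER-associated degradation and heat-shock genes, and 7 and 0 for the 42 general stress genes. Other lists had as many, with 9 and 0 for post-diauxic genes and 7 and 0 for both respiration genes and Yap1 targets. Proteasome and sulfur amino acid genes had 6 and 0, and phosphate starvation genes 0 and 13. Over all 5498 probe sets this block called 783. Of all probe sets 472 (8.58%) had no overlap between the groups, against 1.67% by chance if the 10 arrays are independent. With near-identical arrays averaged 644 (11.7%) had none, against 13.3% by chance. Camera called 9 of 29 lists higher and 3 lower, and only the ER chaperone list held with an estimated correlation. Under the set and replicate blocks no list held with one (lowest adjusted p 0.235 and 0.542). With the replicate block camera called 11 lists higher and 4 lower. With near-identical arrays averaged limma called 0 probe sets (219 at an unadjusted p under 0.05; lowest adjusted p 0.0515; camera 6 lists higher, 2 lower). Without αENaC 1 or αENaC 2 the calls were 11 higher with 1 or 2 lower.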

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

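The unnamed probe sets were examined only after the results for named genes were seen, and the outlier test was fixed beforehand. Among the 7 controls, 98 groups of values (69 genes and 29 lists) were tested for a lowest or highest array whose gap to its neighbour exceeds 0.568 of the whole range, and 9 exceeded it; chance gives about 1 in 20 groups, or 4.9, if the controls are independent. Controls 1 and 2 and controls 5 to 7 are near-identical, control 3 is the only control of set 2, and 6 of the 9 are in control 3, so the 4.9 does not hold for them. In control 3, INO1 was far below the other controls at −1.45 on the log2 scale. HSP82 was far above them in control 3 at 2.27, as were AHA1 at 1.93 and MDH2 at 1.29. ZRC1 in control 3 was far below the others at 1.53, and the heat-shock list in control 3 was far above them, at 0.29 relative to the mean of the controls. In control 4, PDI1 stood above the others at 3.38, as did the iron regulon list at 0.87 and the list of genes specific to a-mating-type cells at 0.18.

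Among the 3470 probe sets with no gene name here, 348 of which lay above background on average, 11 were higher and 3 lower in αENaC at an adjusted p of 0.05 with limma, and 28 were higher and 33 lower with the set as a block. The 2 rises with the smallest p were 1.87 ± 0.14 and 1.18 ± 0.11 on the log2 scale (SE, n = 3 and 7), both below background in the controls and over all arrays; the αENaC mean lay above it for the first, at −1.98, and below it for the second, at −2.92. The 2 falls with the smallest p were −0.87 ± 0.11 and −0.32 ± 0.05. What these probe sets measure was not tested.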

How the results depend on the processing

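The alternatives with other pseudocounts, without quantile normalization, on the z scores, with near-identical arrays averaged and with set 1 alone were chosen only after the data were seen. The ER chaperone list was called under all 31 alternatives (median 0.21 to 0.42, adjusted p 6.51e-13 to 0.0321), but not with an estimated correlation joined to the set block (0.235) or the replicate block (0.542), and the unfolded protein response list under 30 (adjusted p 1.53e-15 to 0.0603), with a median of 0.0050 under median centring. Against 75 probe sets higher and 20 lower, array weights gave 2365 and 1761 (their fit stopped before converging), the fixed set block 406 and 377, the random set block 358 and 259, median centring 33 and 9, no quantile normalization 45 and 1, the 3 controls of sets 1 and 2 alone 18 and 2, and set 1 alone 1559 and 1750. The replicate block, which uses 3 against 3 arrays with 2 residual degrees of freedom, gave 0 and 0 in limma (1127 at an unadjusted p under 0.05). Averaging near-identical arrays also gave 0 and 0 (219 at an unadjusted p under 0.05). Z scores gave 4 lower, for which no 2-fold count was made, and a floor at background 45 lower. Leaving out 1 array gave 11 to 162 higher and 1 to 86 lower. Leaving out 1 array ended the list calls of general stress and Yap1 genes (control 1 or 2), ribosomal proteins (αENaC 2) and meiosis genes (αENaC 2 or control 1, 2 or 3). It made those of ribosome biogenesis (αENaC 3 or control 3, 4 or 7), cell wall (αENaC 3 or controls 4 to 7), ergosterol (control 1), post-diauxic (control 4) and ER translocation genes (αENaC 3). Without αENaC 1 the calls were 11 and 1, without αENaC 2 11 and 2, without αENaC 3 151 and 86, without control 3 162 and 75, without control 4 104 and 32, and without controls 5, 6 or 7 40 with 4, 5 and 4. Lists, 9 higher and 3 lower, were 5 and 5 with median centring, 5 and 6 without quantile normalization, and 1 and 0 with an estimated correlation, where the unfolded protein response, at 0.20, was lost; lower lists numbered 6 on z scores, 0 with fry, 5 in set 1 alone and 2 to 5 with 1 array left out (5 without αENaC 3). The replicate block ended the list calls of the pyrimidine genes (adjusted p = 0.436; 0.000419 to 0.884 over alternatives) and the zinc and copper genes (adjusted p = 0.396; 3.42e-06 to 0.865), made those of ribosome biogenesis, amino acid synthesis, respiration, post-diauxic and cell wall genes, and changed no other list call. Signs turned as follows for named genes and lists, though not every list without a call is given. Median centring gave KAR2 −0.049, PDI1 −0.30, HAC1 −0.12, HSP12 −0.10, PMA1 −0.43, Yap1 targets −0.062, pyrimidine genes −0.0055, meiosis −0.049 and glycolysis −0.49; no quantile normalization gave PDI1 −0.089, PMA1 −0.22, glycolysis −0.27 and respiration −0.011. Z scores gave HSP12 −0.22, PMA1 −0.22, NHA1 0.00019, ER translocation 0.12, glycolysis −0.58 and meiosis −0.047. Array weights gave HSP12 −0.56, URA3 0.27 and phosphate genes 0.076, whose call ended (adjusted p = 0.561; 1.80e-08 to 0.561 over alternatives). They also turned lists without a call: vesicle coats −0.031, ribosome biogenesis 0.021, sulfur −0.072, iron 0.38 and respiration −0.10. HSP26, at −0.27, was 1.02 with the fixed set block, the replicate block or the 3 controls of sets 1 and 2, 0.86 with the random set block and 2.26 in set 1 alone, where ergosterol was −0.15 and zinc and copper −0.023 against a test direction of higher. With 1 array left out HSP26 ranged from −0.69 to 0.075 (above 0 without control 4), HSP12 from −0.067 to 0.49 (below 0 without control 1 or 2) and URA3 from −0.11 to 0.063 (above 0 without αENaC 3 or controls 1, 2 or 3). Pyrimidine genes were at −0.0058 with the fixed set block, the replicate block or the 3 controls of sets 1 and 2, and at −0.046 in set 1 alone, and the floor left the meiosis list no median difference. The cause of these changes was not tested. For bright genes and lists, the scalings without quantile normalization also carry the narrower range of the set 1 arrays given with the ribosomal protein genes. Of the 43 called genes named in the text, 43 kept their sign under each alternative except median centring (42, KAR2 turning), the floor at background (42, as NDJ1 lay below it on all arrays and was left with no difference) and the filter on dim probe sets (40 of 40 tested). Since they were chosen as called, their signs are little evidence. All 43 kept their call with the set as a block. Only 8 did with the 3 controls of sets 1 and 2, and 9 and 10 without αENaC 1 or 2. The number was 20 without quantile normalization, 24 with median centring, and 0 with the replicate block or near-identical arrays averaged. Lists under the random block, array weights and intensity trend were tested from gene statistics (cameraPR). Signal was 25.6 to 44.4 times the median of probe sets named outside the S. cerevisiae annotation, with each array's lowest score taken as 0. This limits genes near background such as NDJ1.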

Other observations

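The tests of sets, scaling, growth state, absence of αENaC and URA3 dose below were chosen only after the results were seen, while the counts over other splits of the arrays were planned. Single members of several metabolic lists rose. MDH2, a malate dehydrogenase of gluconeogenesis, rose by 0.83 ± 0.11 (SE, n = 3 and 7; adjusted p = 0.00715) and was the 1 call among 52 respiration genes. The carnitine acetyltransferase gene YAT2 rose by 0.61 ± 0.10 (adjusted p = 0.0165), the 1 call among 26 post-diauxic genes. SNZ1, of vitamin B6 synthesis, rose by 0.86 ± 0.14 (adjusted p = 0.0158), the 1 call among 56 amino acid synthesis genes. SRL3 rose by 0.69 ± 0.15 (adjusted p = 0.0462), the 1 call among 22 calcineurin targets, and INO1 was the 1 call among 26 phospholipid synthesis genes. Of 29 Yap1 targets of oxidative stress, AAD4 rose by 0.54 ± 0.08 (adjusted p = 0.0103) on a probe set with shared probes (3 higher and 1 lower when adjusted over the list alone). The Yap1 list was higher by a median of 0.14 that was −0.06 with median centring (adjusted p = 0.0255, and adjusted p = 0.181 with an estimated correlation), and it passed under 22 of 31 alternatives.

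No shift passed the list test for the groups that follow, but several passed under alternatives. The replicate block called respiration (adjusted p = 6.33e-06), post-diauxic (6.33e-06) and cell wall genes (0.000121) higher and amino acid synthesis genes (0.0144) lower. None of these held when that block was joined with an estimated correlation (adjusted p = 0.646, 0.542, 0.542 and 0.709). Over 31 alternatives their adjusted p reached from 2.52e-06, 7.84e-07, 0.000121 and 0.000253 to 0.980, 0.980, 0.952 and 0.980. Respiration genes were at 0.03 (adjusted p = 0.809), but at −0.011 without quantile normalization, where the list was called lower (adjusted p = 0.0146), and −0.23 with median centring. Glycolysis genes, 22 measured and none called, were at 0.00 with a mean of −0.01 (adjusted p = 0.983), but at −0.49 with median centring, −0.27 without quantile normalization and −0.58 on z scores. In each of these the list was called lower (adjusted p = 0.00196, 3.06e-08 and 0.000693, in a range of 3.06e-08 to 0.988 over 31 alternatives). As for the ribosomal protein genes, these falls cannot be told apart from the narrower range of the set 1 arrays. In set 1 alone the glycolysis list was called higher, at 0.06 (adjusted p = 0.0261). Post-diauxic genes were at 0.10 (adjusted p = 0.279), but at −0.07 with median centring and −0.01 on z scores. Amino acid synthesis genes were at 0.02 against a test direction of lower (adjusted p = 0.842), and called lower at −0.25 with median centring (adjusted p = 0.00516) and −0.03 without quantile normalization (adjusted p = 0.000253). With median centring the signs also turned for sulfur amino acid genes (29 measured, 0.02, adjusted p = 0.809, to −0.17), ergosterol synthesis (30 measured, 0.22, adjusted p = 0.172, to −0.02) and phospholipid synthesis (0.05, adjusted p = 0.809, to −0.19). In set 1 alone ergosterol genes were called lower at −0.15 (adjusted p = 0.0443), while without control 1 they were called higher at 0.27 (adjusted p = 0.0312, in a range of 0.0312 to 0.999 over 31 alternatives). With median centring the signs also turned for cell wall genes (33 measured, 0.09, adjusted p = 0.0554, to −0.12) and vesicle coats (36 measured, 0.02, adjusted p = 0.809, to −0.14). Vesicle coat genes were at 0.19 and called higher on z scores (adjusted p = 0.000693, in a range of 0.000693 to 0.992 over 31 alternatives). The iron regulon, 29 measured, was at −0.04 (adjusted p = 0.809), and at 0.16 without quantile normalization. Calcineurin targets were at 0.17 (adjusted p = 0.254). When adjusted over the list alone, 1 member was higher in each of respiration, post-diauxic, phospholipid and sulfur genes, and 1 was lower in the latter pair. In amino acid synthesis and cell wall genes 2 were higher, in calcineurin targets 2 were higher and 2 lower, and in glycolysis, ergosterol, iron and vesicle coat genes none was called.

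Genes specific to a-mating-type cells, 8 measured and none called, had a median level below background in the controls (−2.67 in set 1), but MFA1 lay above it at −0.63. Their median difference was −0.14 (adjusted p = 0.487; 0.01 without quantile normalization). On z scores the list was called lower (adjusted p = 0.0264, in a range of 0.0264 to 0.999 over 31 alternatives). Genes specific to α-mating-type cells, 4 measured and none called, were high in the controls (medians 2.83, 2.45 and 1.97 in sets 1 to 3) and at 0.16 in the comparison against a test direction of lower (adjusted p = 0.983; −0.06 with median centring). Among 23 pheromone-response genes 2 rose and 2 fell (also 2 and 2 when adjusted over the list alone), with FUS3 at 0.36 ± 0.07 (adjusted p = 0.0392) and HO and FAR1 lower, and the median was −0.10 (adjusted p = 0.379; 0.06 without quantile normalization). Meiosis genes were higher by a median of 0.07, with 2 of 31 rising (4 when adjusted over the list alone), but at −0.05 on z scores and with median centring (adjusted p = 0.0275, and adjusted p = 0.368 with an estimated correlation). On z scores the call was reversed, to lower (adjusted p = 0.000377, in a range of 0.000377 to 0.368 over 31 alternatives). The median level of the list lay below background in the controls (−2.89 in set 1). Besides HOP1, SPO11 was at 0.58 ± 0.11 (adjusted p = 0.0293), below background in the controls.

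ER chaperone genes were higher on all 3 αENaC arrays. The smaller of the within-set medians was 0.249, above 2 SD of the control arrays (SD 0.045), which argues against a difference between sets; without quantile normalization the median of 0.42 was at percentile 100 of 10000 random lists matched on expression (central 95% 0.0046 to 0.27), which argues against scaling as the whole cause. An adjusted p of camera as small arose in 1 of 100 splits of the arrays, the real one, but these splits ignore the sets and the numbered pairs, and a split with control 7 in place of αENaC 2 reached 9.87e-09. For the unfolded protein response list 2 of 100 splits gave a camera p as small. There the split with control 7 reached 8.71e-10, below the real 2.17e-09. The ER chaperone list was not called with an estimated correlation under the set block (adjusted p = 0.235) or the replicate block (0.542). Whether the αENaC protein or the plasmid otherwise has this effect was not tested and stays open.

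Of 100 of the 120 splits of the arrays into 3 and 7, 4, the real one among them, gave as many calls as its 95 probe sets. That share is under 0.05, but these splits ignore the sets and the numbered pairs. Near-identical arrays cannot be exchanged freely, so the share cannot exclude chance. Limma called 0 probe sets with the replicate block, on 3 against 3 arrays (1127 at an unadjusted p under 0.05). It also called 0 with near-identical arrays averaged (219). Other splits with high counts were controls 5 to 7 (130) and αENaC 1 with controls 1 and 2 (590). The highest other split gave 686. That split set αENaC 2 with controls 1 and 2 against the rest, which follows set 1 and points to a structure of the arrays by set; with the set as a block the real comparison gave 783. For the 12 lists, 32 of 100 splits gave as many, the highest other 17, so chance cannot be excluded for their number. Within the sets 1 of 6 splits gave as many as 783, the real one, and the highest other 544, and 6 splits are too few for a share under 0.05. Of the splits drawn, 7 part all 3 numbered pairs, and the highest other count among them was 53 probe sets and 12 lists.

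General stress genes were lower in the controls of set 1 (median 0.15) than in those of set 2 (1.56) and set 3 (1.40). The median of the gene by gene differences between the controls of sets 3 and 1 was 0.98, which is not the difference of those medians. It was at percentile 100 of 10000 random lists matched on expression (central 95% −0.19 to 0.09). The values were quantile normalized, so this argues only against a remaining shift shared by genes of like level. The list was examined because it split by set, and random lists do not move together, so the percentile cannot exclude chance. The lowest of the 5 other controls lay 0.709 above the highest of set 1 (SD 0.285 in set 3). This gap restates the pattern itself, and all controls lack αENaC. So the test cannot decide on the absence of αENaC as the cause, and nothing is concluded from it. Of 70 ribosome biogenesis genes, 66 were higher in the controls of set 1 than in those of both other sets, consistent with a difference in growth or stress state of the cultures, which stays open. The difference of the list's shift between sets 2 and 1 passed camera (adjusted p = 2.04e-19) but not with an estimated correlation (adjusted p = 0.789).

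URA3 was lower in αENaC within both sets, and URA1, URA4 and URA8 were higher within both (URA1 by 0.45 and 0.27, URA4 by 0.57 and 0.36, URA8 by 0.83 and 0.41). With the set as a block the URA3 difference was −0.49 (adjusted p = 0.00892, in a range of 0.000547 to 1 over 28 alternatives), and with array weights and no block it was 0.27. A lower dose of the plasmid marker could raise the other uracil genes if the control vector carries the same URA3 marker, which the labels do not state and which was assumed here. The controls of set 3 have lower URA3 than those of sets 1 and 2, but their mean of URA1 and URA4 was lower too. The difference, set 3 minus sets 1 and 2, was −0.424 (2-sided exact permutation p = 0.0286, the smallest that 4 against 3 arrays can give). This cannot be told apart from the other differences between these controls, since 28.5% of probe sets differ between them.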
